A study of Mus musculus with 24 samples.

How the data were processed

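The measurement was total RNA sequencing of small intestinal crypts from C57BL6/J mice of both sexes at 2, 18 and 26 months of age. Each of the 6 groups of sex and age held 4 libraries, 24 in all. Per the labels, the mice were group housed and young mice were 2 months old. Crypts were separated from the tissue with EDTA after scraping away villi, ribosomal RNA was depleted with a Ribo-Zero Gold kit, and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand of a transcript. Reads from stretches where genes overlap on opposite strands therefore carry no strand. Depending on the counting settings, they can be given to a gene of the pair or to none.

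The deposited values were raw read counts per gene symbol, with 1 count table per library and no scaling. Per the submitters' processing notes, the authors used FastQC 0.11.5, TopHat2 2.1.0 with Bowtie and HTSeq 0.11.2 on genome build mm9. The annotation release, the strand setting of the counting and any read filter are not stated there. Each table held 35002 symbols, the same in all libraries. One of them was a full stop that names no gene and took between 0.00166% and 0.0043% of a library's counts. It was removed, which left 35001 genes. Counts of reads outside genes or with several genes were not among the values. Total counts per library ran from 4839549 to 29776197. Read length, read pairing and the date of sequencing were not used here.

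Symbols were matched by exact name to GENCODE vM1 on NCBIM37, the assembly also called mm9. A gene of the same name was found for 33638 of the 35001 symbols, and 342 symbols had more than 1 locus. Gene type, position, exon length, overlapping genes and neighbours came from this match. Transcripts of coding genes were aligned to annotated pseudogenes with minimap2 2.31, and a pseudogene with at least 95% identity over at least 200 bases was counted as a near-identical copy. At least 1 such copy was found for 1427 coding symbols.

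Each library's sex was checked from Xist and the 4 tested Y-linked genes of a fixed list, and all 24 libraries matched their labels. Libraries of a group were checked for being separate measurements. The chi-square statistic per degree of freedom between the counts of a pair of libraries of a group was between 3.23 and 59.8, where copies of the same library would give about 1. The correlation of log2 CPM (counts scaled to a total of 1000000) within a group was between 0.970 and 0.993. The replicates are labelled as separate samples of group-housed mice, and the labels do not give a litter, cage or day.

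Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 6 groups, with a minimum count of 10 and a minimum total of 15, which left 16677 genes. Library sizes were scaled with trimmed mean of M values (TMM) factors. A quasi-likelihood model with 1 coefficient for each of the 6 groups was fitted to all 24 libraries, so that all groups shared an estimate of the spread. The 10 comparisons were contrasts of this model. They were 26 against 2 months, 18 against 2 months and 26 against 18 months as means of the female and male changes, the changes of 26 and of 18 against 2 months in each sex, the difference between sexes in each of these changes, and males against females as a mean over the 3 ages. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are fitted log2 values with standard errors (SE) derived from the test statistic, or the corresponding ratio. Levels are CPM on TMM-scaled library sizes, given as the mean and standard deviation (SD) of 4 libraries.

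A fold change against libraries that all held 0 reads was not taken from the model. It was replaced by a lower bound, the reads of the other sex over the sum of its 12 TMM-scaled library sizes, divided by 3 counts over the sum for the sex without reads. Such floors cover counting error only, since amplified reads are not independent molecules.

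The sets of genes were 43 lists. They covered MHC class II presentation, MHC class I presentation, the interferon gamma response, the type I interferon response, the intestinal stem cell, the regenerative fetal-like epithelium, Wnt target genes, the Notch pathway, the Paneth cell, the goblet cell, the enteroendocrine cell, the tuft cell and the enterocyte. They also covered the antimicrobial and barrier response, the cell cycle, replication-dependent histones, p53 target genes, senescence and secretory factors, NF-kB target genes, the tight junction, fatty acid oxidation and PPAR targets, cholesterol synthesis, the unfolded protein response, immediate early and heat shock genes, the xenobiotic and NRF2 response, the circadian clock, ribosomal proteins, nuclear oxidative phosphorylation and mitochondrially encoded genes. The last group was of other cells, regions and sex, with the T cell and intraepithelial lymphocyte, the B cell and plasma cell, immunoglobulin loci, the macrophage and neutrophil, the mast cell, fibroblast and smooth muscle, endothelium, the enteric neuron and glia, the red blood cell, the pancreatic acinar cell, the proximal small intestine, the ileum, Y-linked genes, and X-linked escape genes with Xist. Each list was tested in 5 comparisons with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The p-values were adjusted over the lists of a comparison, and lists with fewer than 4 tested members got no test. The same tests were made with an estimated correlation and with fry, which asks whether the members of a list move on balance in a direction and does not compare them with other genes. For each list, the members called over all genes and the members called when p was adjusted over the list alone were counted.

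Genes were named by a fixed rule. In the 3 comparisons over both sexes against 2 months or between sexes, the named genes were the 8 highest and the 8 lowest fold changes among called genes with a mean of at least 1 CPM and with the same sign in both sexes or at all ages. Y-linked genes, Xist, immunoglobulin and T cell receptor segments, and symbols of the Gm, LOC, Rik, Mir, Snor and -ps forms were left out. Other clone numbers and small RNA names, such as AC115697.1, Y_RNA and mmu-mir-689-2, stayed in. In the other 7 comparisons, the named genes were the 5 with the smallest adjusted p under the same limits. Each list was represented by up to 3 called members with the smallest adjusted p. Genes outside this rule are named as examples of a pathway, tissue or library.

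The comparisons, tests, thresholds, gene lists, naming rule and a first set of alternatives were chosen before the data were examined. These alternatives were median-of-ratios size factors in the same edgeR model, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no low-count filter, a filter of at least 1 CPM in at least 8 libraries, the replicate number of the labels as a block, a fit of only the libraries compared, leaving out each library in turn, and the list tests with an estimated correlation and with fry. A set of 5 more was chosen after the data were seen, namely leaving out the 3 shallow male 26-month libraries, leaving out 5 libraries with stomach transcripts (each of which leaves 1 male 26-month library, replicate 4, with the spread taken from the other groups), thinning all libraries to 4839549 counts, leaving out short RNA genes, and leaving out coding genes with near-identical copies together with pseudogenes and genes under 200 nt.

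For the overlap of the calls at 18 and at 26 months, which share the 2-month libraries, groups without any age change were simulated 10 times, and the overlap was also computed with separate 2-month libraries in each comparison. Counts of calls were compared with those of other splits of the same libraries, 35 splits for a comparison of 8 libraries of a sex and 100 drawn splits otherwise. A principal component analysis used the 1000 most variable genes.

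The procedure was tested on simulated data with 200 changed genes per comparison at the depths of the real libraries. In 26 against 2 months over both sexes, edgeR recovered 64.2% of the genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 7 false calls. For the sex difference in that change it recovered 25.4%, 56.7% and 83.3%, with 4 false calls. Camera called the changed list in all 5 comparisons and 0 of 40 unchanged lists in each. Other splits of real libraries gave up to 24 lists. Tables and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.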

Results

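The data were read counts of total, ribosome-depleted RNA from small intestinal crypts of C57BL6/J mice. Crypts are the pockets of the intestinal lining that hold the stem cells, their dividing progeny and Paneth cells. Females and males of 2, 18 and 26 months made 6 groups of 4 libraries each. Total counts ranged over the 4 libraries of a group from 15795073 to 20464287 in 2-month, 18212095 to 29776197 in 18-month and 16780405 to 28945579 in 26-month females. In males they ranged from 10916250 to 16263383 at 2 months, 11438905 to 26270200 at 18 months and 4839549 to 10998921 at 26 months. Within the 26-month males, replicates 1 to 3 had 4839549 to 5418764 counts and replicate 4 had 10998921.

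Mitochondrially encoded genes took 2.53% ± 0.559 (SD, n = 4) of the counts in 26-month males. Their share in the other groups was 1.43% ± 0.094 in 2-month, 1.39% ± 0.187 in 18-month and 1.56% ± 0.128 in 26-month females, and 1.69% ± 0.198 in 2-month and 1.40% ± 0.127 in 18-month males (SD, n = 4). The stomach gene Gkn2 was between 2.25 and 54.1 CPM in 5 libraries. These were replicate 3 of the 2-month females, replicate 2 of the 26-month females and replicates 1 to 3 of the 26-month males. It was at most 0.0818 CPM in the other 19 libraries. Xist, the RNA of the inactive X chromosome, was between 1462 and 2325 CPM in the 12 female libraries and between 1.08 and 3.47 CPM in the 12 male libraries. The first principal component of the 1000 most variable genes (60.7% of variance) split the sexes, the second held 9.8% and the third 5.4%.

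**Figure D1:**
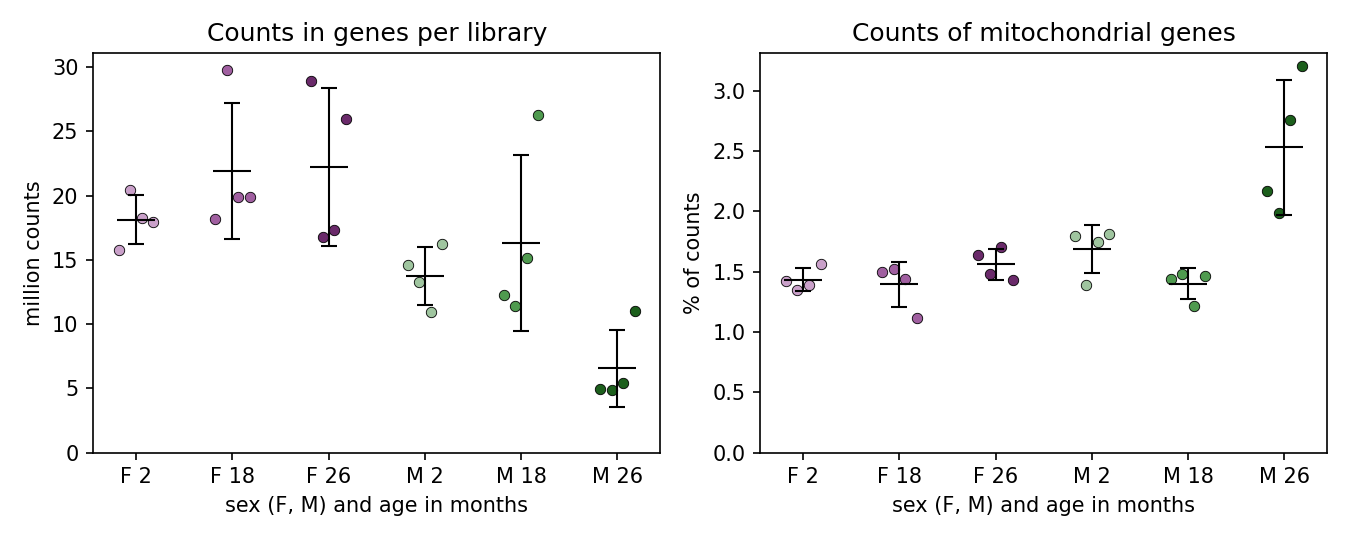
Total counts, in units of 1000000, and the percentage of counts from mitochondrially encoded genes in each library, by group, with points for libraries and bars for the mean and SD of 4 libraries. The 26-month males had a mitochondrial share of 2.53% ± 0.559.

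**Figure D2:**
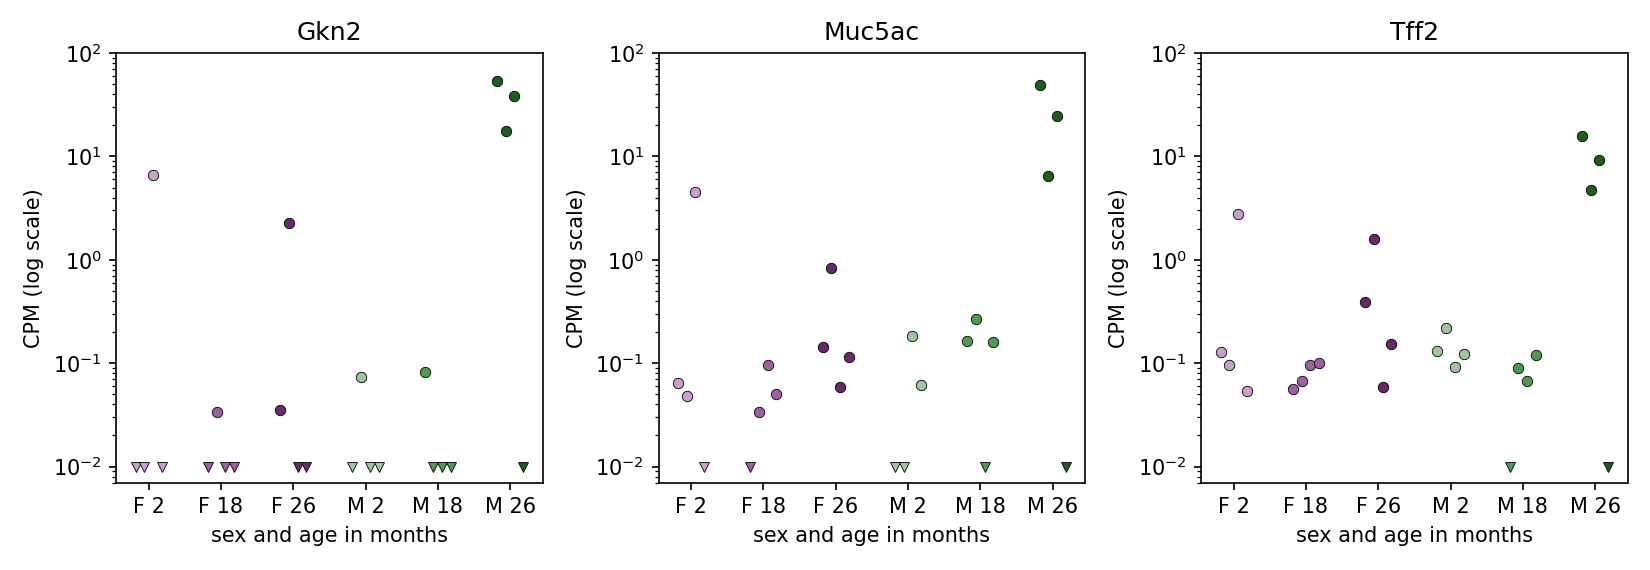
CPM of the stomach genes Gkn2, Muc5ac and Tff2 in each library on a log axis, by group, with triangles at the lower edge for libraries below 0.01 CPM. Gkn2 was between 2.25 and 54.1 CPM in 5 libraries and at most 0.0818 CPM in the other 19.

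The first comparison asked which crypt transcripts differed between 26-month-old and 2-month-old mice over both sexes, the widest age span of a study of the ageing mouse intestine. Of 11 genes of MHC class II presentation, by which cells show antigen to helper T cells, 7 were called higher, though the list was not called with an estimated correlation (adjusted p = 0.736). H2-Aa, the alpha chain of that complex (mm9 chromosome 17, 34406276 to 34424772), went from 21.3 ± 7.35 to 262.9 ± 42.9 CPM in females and from 43.5 ± 20.5 to 288.8 ± 148.7 CPM in males (SD, n = 4). All 4 libraries of each older group were above every 2-month library of their sex. Its invariant chain partner Cd74 (chromosome 18, 60963502 to 60972300) went from 121.5 ± 53.3 to 788.6 ± 154.1 CPM in females and from 210.3 ± 67.8 to 736.1 ± 298.9 CPM in males. Serpinb5, a protease inhibitor of the serpin family (chromosome 1, 108757750 to 108779925), was 10.5-fold higher (SE 0.25 on the log2 scale, adjusted p = 2.22e-09). Lin28b, which blocks maturation of let-7 microRNAs, was 18.8-fold higher from 0.131 ± 0.0875 CPM in 2-month females. The stem cell receptor gene Lgr5 (chromosome 10, 114887367 to 115024836) fell from 49.9 ± 10.4 to 31 ± 8.88 CPM in females and from 41.9 ± 5.05 to 23.1 ± 8.26 CPM in males. In each sex 4 of 4 libraries were below all 2-month libraries of that sex.

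Of 16677 genes tested with edgeR, 2671 were called, 1522 higher and 1149 lower at 26 months. The change was at least 2-fold in 180 of the higher and 149 of the lower genes. The lowest fold change among abundant genes was that of Rps4y2 (chromosome 6, 148303178 to 148304120), an autosomal gene named for ribosomal protein S4 that lies inside Tmtc1 on the opposite strand. Its log2 fold change was -4.37 ± 0.25 (SE, adjusted p = 2.98e-11). Also lower were Pex5l, related to a receptor for peroxisomal proteins (-3.87 ± 0.40), the germ cell gene Tex15 (-3.06 ± 0.35), Ric3, a chaperone of acetylcholine receptors (-2.89 ± 0.28), and AI467606 (-2.86 ± 0.26). Further lower genes were Nrn1, which encodes neuritin (-2.60 ± 0.25), the cell junction gene Amotl1 (chromosome 9, 14346410 to 14447973, -2.54 ± 0.20) and the lectin-like gene Clec2j (-2.47 ± 0.62, adjusted p = 0.00931). The highest were AC115697.1, an annotated microRNA inside Fgfr2 on the opposite strand (chromosome 7, 137977951 to 137978037), at 28.6-fold, Lin28b, the chemokine receptor gene Ccr2 (3.55 ± 0.32) and Serpinb5. They were followed by Retnlb, the glutamate decarboxylase gene Gad2 (3.18 ± 0.26), H2-Aa at 9.03-fold (adjusted p = 1.91e-08) and the collagen receptor gene Ddr2 at 7.86-fold. Retnlb, a goblet cell defence gene, was 9.48-fold higher (adjusted p = 0.00901). Without replicate 4 of the 26-month males its log2 fold change was 0.46 ± 0.80 (adjusted p = 0.752). H2-Aa overlaps H2-Ab1, Pex5l overlaps 4930419G24Rik, Ric3 overlaps Tub, Gad2 overlaps AL928693.1 and Ddr2 overlaps 3110045C21Rik. Where such pairs are on opposite strands, how the reads of the shared stretch were counted is not known.

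**Figure D3:**
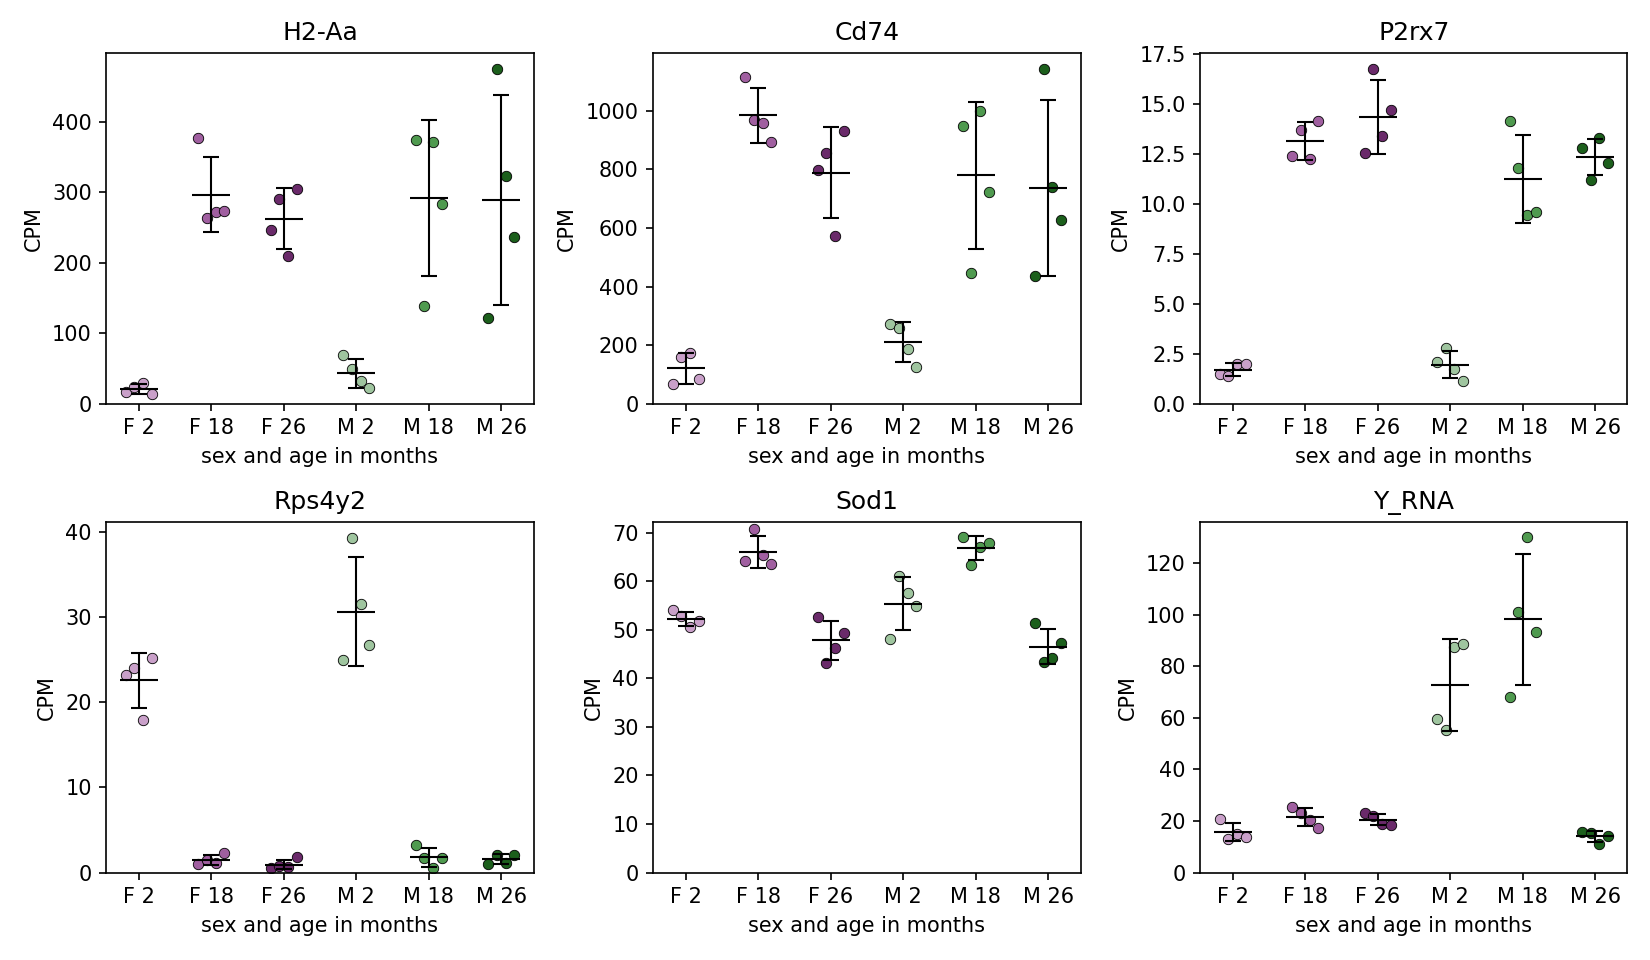
CPM of H2-Aa, Cd74, P2rx7, Rps4y2, Sod1 and Y_RNA in each library, by group, with points for libraries and bars for the mean and SD of 4 libraries. H2-Aa in females went from 21.3 CPM at 2 months to 296.9 CPM at 18 and 262.9 CPM at 26 months, and Rps4y2 from 22.6 to 1.49 and 0.944 CPM.

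Of the 43 gene lists, camera called 11 in this comparison at its preset correlation. With an estimated correlation it called 0, and the smallest adjusted p = 0.736 was that of MHC class II presentation. In that list 7 of 11 tested genes were called, all higher, and 7 adjusted over the list alone (median log2 fold change 2.07, camera adjusted p = 2.19e-09). H2-DMb1 was at 2.76 ± 0.25 and Cd74 at 2.25 ± 0.22. MHC class I presentation, which shows peptides to cytotoxic T cells, had 15 of 21 genes higher, 17 adjusted over the list alone (median 0.49, camera adjusted p = 2.57e-09; 0.748 with an estimated correlation). It was led by H2-M3 (0.88 ± 0.11), the light chain gene B2m (0.56 ± 0.08) and the immunoproteasome gene Psmb8 (1.53 ± 0.24). In the interferon gamma response 7 of 24 genes were higher, 15 adjusted over the list alone (camera adjusted p = 9.59e-05; 0.748 with an estimated correlation). Among them was the guanylate binding protein gene Gbp8 (1.26 ± 0.21). The antimicrobial and barrier response had 5 of 12 genes higher, 6 adjusted over the list alone (camera adjusted p = 0.0281; 0.748 with an estimated correlation). The phospholipase gene Pla2g5 was at 2.46 ± 0.32 and Nos2, which makes nitric oxide, at 1.02 ± 0.25. Without the 5 libraries with stomach transcripts, Nos2 was at 0.46 ± 0.29 (adjusted p = 0.338).

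Ribosomal proteins had 32 of 80 genes higher and 2 lower, 42 and 2 adjusted over the list alone (median 0.17, camera adjusted p = 3.47e-10; 0.748 with an estimated correlation). An example was Rps18 (0.41 ± 0.06). Nuclear genes of oxidative phosphorylation had 21 of 73 higher and 1 lower, 30 and 1 adjusted over the list alone (camera adjusted p = 2.42e-08; 0.75 with an estimated correlation). The complex I gene Ndufa10 was at 0.26 ± 0.06 and the testis-type subunit gene Cox6b2 at -1.73 ± 0.42. Replication-dependent histones had 16 of 59 higher, 19 adjusted over the list alone (median 0.16, camera adjusted p = 1e-05; 0.75 with an estimated correlation), such as Hist1h2bl (0.43 ± 0.09), where 45 rose in females and 4 fell in males. The changes of these lists were not separated from a relation of fold change to gene length (Spearman rho -0.208 in females and -0.101 in males). In cholesterol synthesis 8 of 20 genes were higher, 10 adjusted over the list alone (camera adjusted p = 0.00467; 0.75 with an estimated correlation), such as Hsd17b7 (0.47 ± 0.09). The unfolded protein response had 4 of 17 higher, 4 adjusted over the list alone (camera adjusted p = 0.00482; 0.748 with an estimated correlation), with the stress factor Atf4 at 0.27 ± 0.06. Without the 5 libraries with stomach transcripts this list had an adjusted p = 0.0612. The T cell and intraepithelial lymphocyte list had 4 of 22 higher, 5 adjusted over the list alone (median 0.67, camera adjusted p = 0.00168; 0.75 with an estimated correlation). The integrin gene Itgae was at 0.69 ± 0.17, the perforin gene Prf1 at 2.03 ± 0.52 and Cd4 at 1.64 ± 0.47. Fibroblast and smooth muscle genes fell as a list, with 5 of 19 lower and 1 higher, 6 and 1 adjusted over the list alone (median -0.36, camera adjusted p = 0.0339; 0.748 with an estimated correlation). They included the collagen genes Col3a1 (-1.40 ± 0.24) and Col1a1 (-1.33 ± 0.24).

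No other list passed the camera test at 26 against 2 months. Stem cell genes had 2 of 22 higher and 4 lower, 2 and 5 adjusted over the list alone (camera adjusted p = 0.29). Rgmb was at -0.44 ± 0.09 and Lgr5 at -0.78 ± 0.15 (adjusted p = 0.00158). Enteroendocrine cells, which secrete gut hormones, had 3 of 21 higher and 4 lower, 3 and 6 adjusted over the list alone (camera adjusted p = 0.444). The hormone genes Gcg (-0.42 ± 0.07), Ghrl (-0.76 ± 0.13) and Sst (-0.91 ± 0.17) were lower. The tuft cell list had 2 of 16 higher, 2 adjusted over the list alone (camera adjusted p = 0.0656). These were Vav1 (0.72 ± 0.11) and Ptgs1 (0.67 ± 0.18, and 0.48 ± 0.18 with adjusted p = 0.0754 without replicate 4 of the 26-month males). The Paneth cell list had 1 of 15 lower, 1 adjusted over the list alone (camera adjusted p = 0.0624), the lectin gene Itln1 (-0.56 ± 0.17). In the goblet cell list 1 of 16 was lower, 1 adjusted over the list alone (camera adjusted p = 0.537), Rep15 (-0.47 ± 0.11). In the enterocyte list edgeR, DESeq2 and limma-voom each called 0 of 22, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.87). The regenerative fetal-like list had 1 of 11 higher and 1 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.923). They were Ly6a (0.99 ± 0.33) and the growth factor gene Ereg (-0.86 ± 0.18). Wnt target genes had 1 of 17 higher and 1 lower, 1 and 1 adjusted over the list alone (camera adjusted p = 0.59), Ccnd1 (0.59 ± 0.17) and Lgr5. The Notch pathway had 2 of 13 lower, 4 adjusted over the list alone (camera adjusted p = 0.157), the ligand genes Jag2 (-0.54 ± 0.14) and Dll1 (-0.26 ± 0.08).

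Among lists of cell state, the cell cycle had 1 of 31 higher and 1 lower (camera adjusted p = 0.368), Pcna (0.25 ± 0.08) and Cenpf (-0.33 ± 0.10), and 0 and 0 adjusted over the list alone. In p53 target genes 1 of 20 was lower, 1 adjusted over the list alone (camera adjusted p = 0.859), Trp53inp1 (-0.55 ± 0.16). Senescence and secretory factors had 1 of 7 higher and 2 lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.87). They were Tnf (1.01 ± 0.21), Igfbp3 (-1.21 ± 0.24) and Il1a (-0.76 ± 0.23). The type I interferon response had 2 of 23 higher, 1 adjusted over the list alone (camera adjusted p = 0.87), Oasl1 (0.82 ± 0.14) and Ifi44 (0.95 ± 0.30). NF-kB target genes had 1 of 12 higher, 1 adjusted over the list alone (camera adjusted p = 0.117), the inhibitor gene Nfkbia (0.23 ± 0.07). The tight junction list had 1 of 17 higher and 4 lower, 1 and 6 adjusted over the list alone (camera adjusted p = 0.0656). The E-cadherin gene Cdh1 was at -0.28 ± 0.07. Fatty acid oxidation and PPAR targets had 2 of 22 higher, 2 adjusted over the list alone (camera adjusted p = 0.118), Acadl (0.34 ± 0.10) and Cyp4a10 (1.58 ± 0.47). Immediate early and heat shock genes had 4 of 15 higher, 4 adjusted over the list alone (camera adjusted p = 0.11), such as Jun (0.35 ± 0.09). The xenobiotic and NRF2 response had 1 of 19 higher, 1 adjusted over the list alone (camera adjusted p = 0.373), Nqo1 (0.46 ± 0.09). The circadian clock had 1 of 17 higher (camera adjusted p = 0.998), Tef (1.04 ± 0.35), and 0 adjusted over the list alone. Mitochondrially encoded genes had 8 of 22 higher, 9 adjusted over the list alone (camera adjusted p = 0.11). Among these were mt-Nd1 (0.64 ± 0.12) and the tRNA gene mt-Tp (0.60 ± 0.12).

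Among lists of other cells and regions, B cell and plasma cell genes had 1 of 12 higher, 1 adjusted over the list alone (camera adjusted p = 0.485), the joining chain gene Igj (1.20 ± 0.37). Immunoglobulin loci had 3 of 30 higher and 1 lower, 3 and 1 adjusted over the list alone (camera adjusted p = 0.233). Igkc was at 1.19 ± 0.35 and went to -0.10 ± 0.44 (adjusted p = 0.92) without the 5 libraries with stomach transcripts. Macrophage and neutrophil genes had 2 of 15 higher, 4 adjusted over the list alone (camera adjusted p = 0.0732), Itgam (0.55 ± 0.14) and Cd14 (0.63 ± 0.16). The mast cell list had 1 of 5 higher, 1 adjusted over the list alone (camera adjusted p = 0.306), the IgE receptor gene Fcer1a (2.29 ± 0.71). The endothelium list had 2 of 7 higher, 2 adjusted over the list alone (camera adjusted p = 0.456), Lyve1 (0.43 ± 0.12) and Vwf (0.67 ± 0.19). The enteric neuron and glia list had 1 of 5 lower, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.998), with Ret at -0.64 ± 0.16. Proximal small intestine genes had 1 of 10 lower, 1 adjusted over the list alone (camera adjusted p = 0.87), the iron reductase gene Cybrd1 (-0.59 ± 0.14). The ileum list had 1 of 10 higher and 1 lower, 1 and 1 adjusted over the list alone (camera adjusted p = 0.998), Cd177 (1.36 ± 0.34) and Muc3 (-0.61 ± 0.17). Of 5 red blood cell genes and 4 Y-linked genes, edgeR, DESeq2 and limma-voom called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.456 and 0.998). The list of X-linked escape genes and Xist had 1 of 5 lower, 1 adjusted over the list alone (camera adjusted p = 0.87), Kdm6a (-0.13 ± 0.04). The pancreatic acinar list had 3 tested genes and no camera test. Its member Cela1, an elastase gene, rose by 1.63 ± 0.10 (adjusted p = 6.69e-11). The median, the mean and the direction of the test differed in sign in the enterocyte, senescence, proximal small intestine, Y-linked and X-linked lists, and the median and the mean in the acinar list.

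The count of 2671 became 1151 without the 5 libraries with stomach transcripts and 1543 with all libraries thinned to 4839549 counts. Calls lost without the 3 shallow male libraries included Igkc (0.02), Nos2 (0.47) and Cd4 (1.46, close to its full value). Each of these 2 reduced sets holds 1 male 26-month library, replicate 4.

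**Figure D4:**
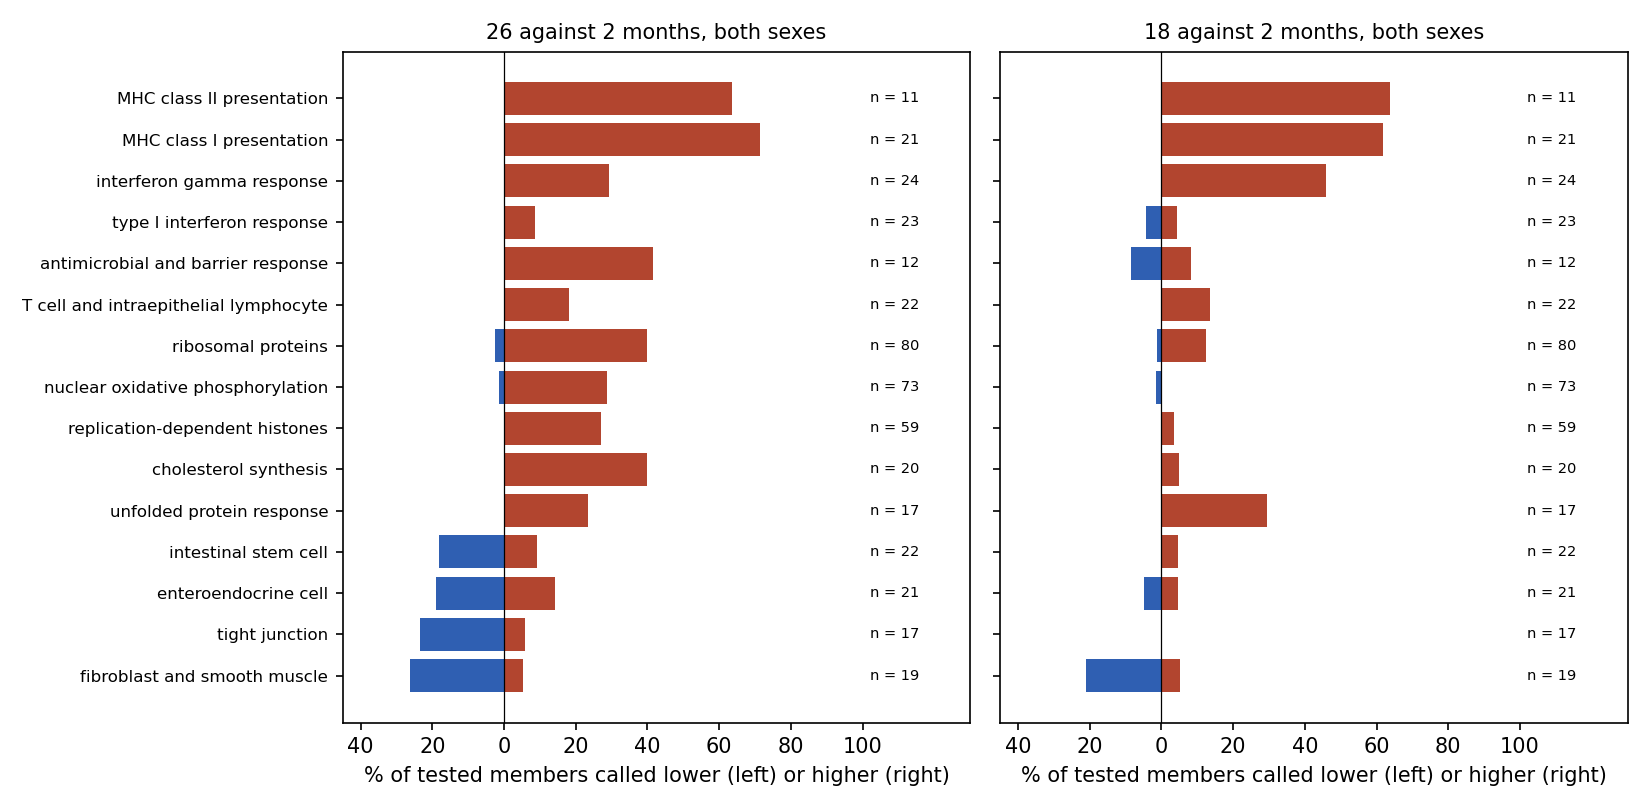
Percentage of the tested genes of 15 lists that were called higher or lower at 26 against 2 months and at 18 against 2 months over both sexes. In MHC class I presentation 15 of 21 genes were called higher at 26 months and 13 at 18 months.

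The second comparison asked which changes were present by 18 months. H2-Aa was at 296.9 ± 53.8 CPM in 18-month females and 292 ± 110.5 CPM in 18-month males (SD, n = 4). The log2 fold change was 3.27 ± 0.27 against 2 months (SE, adjusted p = 1.43e-08). P2rx7, a channel opened by extracellular ATP (chromosome 5, 123093920 to 123141441), went from 1.71 ± 0.322 to 13.1 ± 0.954 CPM in females and from 1.95 ± 0.676 to 11.3 ± 2.2 CPM in males, 6.64-fold over both (adjusted p = 1.7e-12). In each sex 4 of 4 libraries were above all 2-month libraries. Rps4y2 fell from 22.6 ± 3.21 to 1.49 ± 0.578 CPM in females and from 30.6 ± 6.4 to 1.8 ± 1.12 CPM in males. Col1a1 (chromosome 11, 94797538 to 94814356) was at 0.964 CPM in 18-month females against 2.24 CPM in 2-month females. All 4 older libraries were below the younger ones there, and 3 of 4 were in males.

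Of 16677 genes, 1550 were called, 792 higher and 758 lower, and 156 and 107 of these changed at least 2-fold. The lowest were Rps4y2 (-4.02 ± 0.23), Pex5l (-2.98 ± 0.31), Clec2j (-2.72 ± 0.58), AC115697.1 (0.153-fold, adjusted p = 0.0117), AI467606 (-2.52 ± 0.23), Amotl1 (-2.42 ± 0.17), Nrn1 (-2.26 ± 0.22) and the protein disulfide isomerase gene Pdia2 (-2.17 ± 0.17). The highest were Ccr2 (3.46 ± 0.30), H2-Aa, Serpinb5 (3.15 ± 0.24), Ankfn1 (2.96 ± 0.31), the adhesion gene Ceacam10 (7.14-fold), the peptide loading gene H2-DMb1 (7.09-fold), Ddr2 (2.80 ± 0.24) and P2rx7.

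Camera called 11 lists at 18 against 2 months. With an estimated correlation it called 0, and the smallest adjusted p = 0.13 was that of MHC class II presentation. That list had 7 of 11 genes higher, 10 adjusted over the list alone (median 2.21, camera adjusted p = 1.46e-15). Cd74 was at 2.45 ± 0.22. MHC class I presentation had 13 of 21 higher, 16 adjusted over the list alone (camera adjusted p = 1.68e-10; 0.715 with an estimated correlation). H2-Q6 was at 2.24 ± 0.33. The interferon gamma response had 11 of 24 higher, 15 adjusted over the list alone (camera adjusted p = 1.32e-07; 0.715 with an estimated correlation). Gbp8 was at 1.51 ± 0.19 and the tryptophan-degrading enzyme gene Ido1 at 0.80 ± 0.16. Immunoglobulin loci had 5 of 30 higher, 9 adjusted over the list alone (median 0.94, camera adjusted p = 5.48e-05; 0.715 with an estimated correlation). The kappa constant gene Igkc (chromosome 6, 70676429 to 70676751) was at 1.78 ± 0.34. B cell and plasma cell genes had 2 of 12 higher, 5 adjusted over the list alone (camera adjusted p = 0.00395; 0.846 with an estimated correlation), Igj (1.91 ± 0.36) and Cd79a (1.24 ± 0.37). The T cell list had 3 of 22 higher, 10 adjusted over the list alone (camera adjusted p = 0.000191; 0.846 with an estimated correlation). These were Prf1 (2.18 ± 0.48), Cd4 (1.93 ± 0.44) and Lat (1.02 ± 0.28). The unfolded protein response had 5 of 17 higher, 8 adjusted over the list alone (camera adjusted p = 5.89e-05; 0.715 with an estimated correlation). The chaperone gene Dnajb9 was at 0.49 ± 0.07 and Chac1 at 2.05 ± 0.47.

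Ribosomal proteins had 10 of 80 higher and 1 lower, 27 and 1 adjusted over the list alone (camera adjusted p = 3.24e-08; 0.743 with an estimated correlation). In replication-dependent histones 2 of 59 were higher, 2 adjusted over the list alone (camera adjusted p = 0.00193; 0.936 with an estimated correlation), Hist3h2ba (1.29 ± 0.24) and Hist3h2bb-ps (0.90 ± 0.18). Immediate early and heat shock genes had 2 of 15 higher, 3 adjusted over the list alone (camera adjusted p = 0.047; 0.715 with an estimated correlation), Jun (0.32 ± 0.09) and Ier2 (0.28 ± 0.08). Its median of 0.18 was 0.18 without the 3 shallow libraries (adjusted p = 0.0514) and 0.14 without the 5 with stomach transcripts (0.0807). Fatty acid oxidation and PPAR targets were called as a list (median 0.14, camera adjusted p = 0.00807; 0.936 with an estimated correlation). Of its 22 genes edgeR called 0, 0 adjusted over the list alone, with 7 at an unadjusted p under 0.05, and DESeq2 called 0 and limma-voom 2. The median, mean and test differed in sign in the enteroendocrine, mast cell, endothelium, enteric neuron and X-linked lists, and the median and mean in the acinar list. The count of 1550 became 995 without replicate 1 of the 2-month males, 1023 without replicate 4 of the 18-month females, 615 at 4839549 counts per library and 2496 with limma-voom.

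The changes at 18 and at 26 months shared genes. Of the genes higher than at 2 months, 490 were called at both ages, where 72.3 would be shared if the calls were independent. For lower genes the numbers were 375 and 52.2. The 865 shared became 454 without the libraries with stomach transcripts and 377 when thinned. The direction was opposite in 3 genes, and the fold changes had a Pearson r of 0.715 across genes, which are not independent replicates. Both comparisons used the same 2-month libraries, and in 10 simulations without an age change this alone gave a mean r of 0.474. With separate 2-month libraries, 186 higher and 127 lower genes were shared in an arrangement with r of 0.506, and 207 and 119 in its counterpart with r of 0.564.

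The third comparison asked what changed between 18 and 26 months. Sod1, which encodes the cytosolic superoxide dismutase (chromosome 16, 90220987 to 90226567), went from 66 ± 3.32 to 47.8 ± 4.07 CPM in females and from 66.8 ± 2.48 to 46.5 ± 3.65 CPM in males (SD, n = 4), having been at 52.3 ± 1.44 and 55.4 ± 5.42 CPM at 2 months. Lyz1, the Paneth cell lysozyme gene (chromosome 10, 116724852 to 116729924), was at 17310.2 ± 4073.3 CPM in 18-month and 7393.4 ± 1167.9 CPM in 26-month males, and at 12342.5 and 12066.6 CPM in females. AC115697.1 was at 0.759 CPM in 18-month and 273.8 ± 201.6 CPM in 26-month females, and at 0.536 and 45.5 ± 20.7 CPM in males. The glucagon gene Gcg (chromosome 2, 62312587 to 62321707) went from 48.4 to 43.1 ± 4.51 CPM in females and from 47.1 to 30.2 CPM in males.

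Of 16677 genes, 256 were called, 90 higher and 166 lower. The smallest p were those of AC115697.1 (186.7-fold higher, adjusted p = 7.73e-09), Y_RNA, a small cytoplasmic RNA with 24 annotated loci counted together (-1.44 ± 0.14, from 98.1 to 14.1 CPM in males and 21.5 to 20.6 CPM in females), Sod1 (-0.49 ± 0.05, adjusted p = 1.04e-05), which has 1 near-identical pseudogene copy, as well as AC113316.1, an annotated microRNA inside Cdk8 (2.74 ± 0.31), and the polyadenylation gene Cstf2t, inside Prkg1 on the opposite strand (-0.49 ± 0.06). The calls numbered 150 in a fit of only the libraries compared, 52 without the 3 shallow male libraries, 36 without the 5 with stomach transcripts, 112 at 4839549 counts and 487 with DESeq2.

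Camera called 12 lists at 26 against 18 months. With an estimated correlation it called 0, and the adjusted p was 0.854 for all 12 but the histones (0.884). Paneth cell genes fell as a list, with 1 of 15 lower and 9 adjusted over the list alone (median -0.56, camera adjusted p = 1.6e-07), Lyz1 at -0.63 ± 0.13. Stem cell genes had 1 of 22 lower and 3 adjusted over the list alone (camera adjusted p = 0.0054), Rgmb at -0.37 ± 0.08. Enteroendocrine genes had 1 of 21 lower and 4 adjusted over the list alone (camera adjusted p = 0.00843), Gcg at -0.40 ± 0.07. Without the 5 libraries with stomach transcripts Lyz1 was at -0.79 ± 0.17 (adjusted p = 0.0609) and Gcg at -0.40 ± 0.11 (adjusted p = 0.164). Mitochondrially encoded genes had 5 of 22 higher and 10 adjusted over the list alone (median 0.34, camera adjusted p = 4.75e-05). They included mt-Nd1 at 0.67 ± 0.12 and mt-Tn at 0.76 ± 0.14. The antimicrobial list had 1 of 12 higher, 1 adjusted over the list alone (camera adjusted p = 0.0171). It was Retnlb, which was not called without replicate 4 of the 26-month males (0.63, adjusted p = 0.75). Replication-dependent histones had 2 of 59 higher, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0452). Ribosomal proteins had 1 of 80 higher and 1 lower, 1 and 3 adjusted over the list alone (median 0.05, camera adjusted p = 0.0171), Rpsa (0.25 ± 0.06) and Rps28 (-0.44 ± 0.10).

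Another 5 lists were called without any single gene called by edgeR. Nuclear oxidative phosphorylation was higher (median 0.11, camera adjusted p = 4.77e-08), with 0 of 73 called, 0 adjusted over the list alone, 27 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Red blood cell genes were higher (median 0.78, camera adjusted p = 0.00246), with 0 of 5 called, 4 adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. B cell genes were lower (median -0.67, camera adjusted p = 0.0171), with 0 of 12 called, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 by the other tools. Immunoglobulin loci were lower too (median -0.61, camera adjusted p = 0.00387), with 0 of 30 called, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 by the other tools. Wnt target genes were lower (median -0.13, camera adjusted p = 0.0352), with 0 of 17 called, 1 adjusted over the list alone, Lgr5, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The median, mean and test differed in sign in the enterocyte, immediate early, clock, T cell, macrophage, enteric neuron and X-linked lists.

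The next comparisons took each sex alone. In females, P2rx7 rose by 3.06 ± 0.18 at 26 months (SE, adjusted p = 1.99e-10) and in males by 2.67 ± 0.20 (adjusted p = 1.01e-08). Parp3, an enzyme gene of DNA repair that overlaps Rrp9 on the opposite strand, went from 8.93 ± 1.9 to 38.5 ± 1.62 CPM in females and from 10.5 ± 3.4 to 40.4 ± 8.65 CPM in males (SD, n = 4).

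In females 2127 genes were called at 26 against 2 months, 1274 higher and 853 lower. The smallest p were those of P2rx7, Rps4y2 (0.0432-fold), Ceacam10 (10.8-fold), Parp3 (4.30-fold) and the glutamate transporter gene Slc1a3 (1.38 ± 0.13). In males 1252 were called, 693 higher and 559 lower. Here P2rx7, Cela1 (1.84 ± 0.14), Y_RNA (-2.37 ± 0.21), Rps4y2 (-4.20 ± 0.37) and Parp3 (1.93 ± 0.18) had the smallest p. At 18 months 359 genes were called in females, 251 higher and 108 lower, and those with the smallest p were P2rx7 (7.65-fold), Rps4y2 (-3.91 ± 0.32), Ceacam10 (3.04 ± 0.26), Parp3 (1.87 ± 0.17) and Slc1a3 (1.28 ± 0.13). In males 1634 were called, 710 higher and 924 lower. First by p were P2rx7 (2.53 ± 0.19), Rps4y2 (-4.12 ± 0.33), the ubiquitin ligase gene Rnf130, which contains Mir340 (1.04 ± 0.09), Cela1 (2.82-fold) and Ceacam10 (2.63 ± 0.25). The 26 against 2 month fold changes of the sexes had a Pearson r of 0.334 and a Spearman rho of 0.232 across 16677 genes, which are not independent replicates, and the r was 0.103 without the low-count filter. The count at 18 months in females was 110 when thinned, 235 without replicate 2 of the 2-month females and 546 with DESeq2. That in males fell to 495 without replicate 1 of the 2-month males, and that in females at 26 months was 877 without the libraries with stomach transcripts. The male count at 26 months was 630 without its 3 shallow libraries, which leaves 1 library in that group.

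The interaction asked whether the 26 against 2 month change differed between the sexes. The Y_RNA level in males went from 72.7 ± 17.7 to 14.1 ± 2.1 CPM and in females from 15.6 ± 3.52 to 20.6 ± 2.18 CPM (SD, n = 4). Hist1h2be, a histone H2B gene expressed with DNA replication, went from 51.1 ± 5.13 to 87.9 ± 12.4 CPM in females and from 119.4 ± 10.5 to 93.4 ± 18 CPM in males. Dnajb9, a chaperone gene of the endoplasmic reticulum, went from 23.1 ± 2.48 to 16.4 ± 1.13 CPM in females and from 14.0 ± 1.98 to 20.8 ± 2.47 CPM in males.

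Of 16677 genes, 403 were called, 213 with a more positive and 190 with a more negative change in males. The smallest p were those of Y_RNA (0.146-fold, adjusted p = 1.18e-05), Dnajb9 (1.06 ± 0.15), Hist1h2ah (-1.14 ± 0.17), Hist1h2be (-1.13 ± 0.17) and the small Cajal body RNA SCARNA15 (-1.97 ± 0.30), the last 4 with an adjusted p = 0.00175. For 18 against 2 months edgeR called 1 gene, the transcription factor gene Plagl2 (-0.83 ± 0.13, adjusted p = 0.031), while 2328 had an unadjusted p under 0.05, DESeq2 called 140 and limma-voom 65. The count was 110 without replicate 4 of the 18-month females and 0 with the replicate block, the stricter filter, thinning, or without short RNA genes, the shallow libraries or those with stomach transcripts. In these 6, Plagl2 had values from -0.85 to -0.77. The 403 calls became 124 without the libraries with stomach transcripts, with 1 male 26-month library left, and ranged from 141 to 991 when single libraries were left out.

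Camera called 14 lists in the 26-month interaction, and 0 with an estimated correlation. Replication-dependent histones had 35 of 59 genes with a more negative change in males, 51 adjusted over the list alone (median -0.77, camera adjusted p = 7.04e-33; 0.456 with an estimated correlation). Cell cycle genes had 3 of 31 more negative in males, 14 adjusted over the list alone (median -0.36, camera adjusted p = 6.04e-08; 0.608 with an estimated correlation). These were the mitotic genes Cdc20 (-0.72 ± 0.14), Plk1 (-0.75 ± 0.17) and Ube2c (-0.63 ± 0.17). Paneth cell genes had 1 of 15 more negative, 9 adjusted over the list alone (median -0.86, camera adjusted p = 0.000383; 0.662 with an estimated correlation), Defa-rs1 (-1.40 ± 0.37). Tuft cell genes had 3 of 16 more positive, 11 adjusted over the list alone (median 0.96, camera adjusted p = 3.23e-05; 0.608 with an estimated correlation). They were Rgs13 (1.67 ± 0.44), Siglec5 (1.71 ± 0.46) and Chat (2.31 ± 0.62). Replicate 4 of the 26-month males had the highest levels of the tuft cell gene Dclk1 (54.8 CPM against at most 30.5 CPM in the other 23 libraries), and without it the tuft cell median was 0.52 (adjusted p = 0.004). Mitochondrially encoded genes had 4 of 22 more positive, 5 adjusted over the list alone (median 0.52, camera adjusted p = 2.75e-06; 0.524 with an estimated correlation), such as mt-Tp (1.56 ± 0.24). The xenobiotic and NRF2 response had 1 of 19 more positive, 10 adjusted over the list alone (median 1.22, camera adjusted p = 6.55e-08; 0.524 with an estimated correlation), the glutathione synthesis gene Gclm (0.72 ± 0.16). Fatty acid oxidation had 1 of 22 more positive, 1 adjusted over the list alone (median 0.55, camera adjusted p = 2.79e-06; 0.608 with an estimated correlation), Hadhb (0.64 ± 0.17).

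The p53 target genes had 1 of 20 more positive in males, 5 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.0288; 0.524 with an estimated correlation), Pmaip1 (0.84 ± 0.22). Red blood cell genes had 1 of 5 more positive, 4 adjusted over the list alone (median 2.24, camera adjusted p = 0.000258; 0.456 with an estimated correlation), the globin gene Hba-a1 (2.39 ± 0.65). Immunoglobulin loci had 2 of 30 more negative, 3 adjusted over the list alone (median -0.87, camera adjusted p = 0.0471; 0.858 with an estimated correlation). They were Igkv6-23 (-4.34 ± 1.08) and Ighg (-3.94 ± 1.07). A further 4 lists were called without any single gene called by edgeR. The T cell list was more positive in males (median 1.12, camera adjusted p = 0.000135; 0.662 with an estimated correlation). It had 0 of 22 called, 0 adjusted over the list alone, 7 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Mast cell genes were more positive (median 2.87, camera adjusted p = 0.00695; 0.524 with an estimated correlation). They had 0 of 5 called, 3 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 by the other tools. Without replicate 4 of the 26-month males, where Mcpt1 was at 98.4 CPM against at most 30.6 CPM in the other 23 libraries, the mast cell median was 1.62 (adjusted p = 0.0332). Enterocyte genes were more positive (median 0.59, camera adjusted p = 0.000139; 0.824 with an estimated correlation). Here 0 of 22 were called, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom. Their median was -0.22 (adjusted p = 0.903) without the libraries with stomach transcripts. Cholesterol synthesis was more negative (median -0.40, camera adjusted p = 0.00695; 0.835 with an estimated correlation). It had 0 of 20 called, 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Without those libraries the cell cycle (median -0.17, adjusted p = 0.123), p53 target (0.16, 0.0732) and cholesterol lists (-0.32, 0.27) were not called. The median, mean and test differed in sign in the type I interferon, regenerative, senescence, NF-kB, clock, ribosomal, macrophage, fibroblast, enteric neuron and X-linked lists.

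The last comparison was between sexes over 3 ages. Rpl19, a protein gene of the large ribosomal subunit (chromosome 11, 97888024 to 97891806), was at 46.4 ± 5.2 CPM in 2-month males and 5.39 ± 0.35 CPM in 2-month females (SD, n = 4). It has 5 near-identical pseudogene copies. The Paneth cell defensin gene Defa5 (chromosome 8, 22437118 to 22438054) had 0 reads in all 12 female libraries and 31.7 ± 9.05, 71.3 ± 22.2 and 30.2 ± 7.53 CPM in males of 2, 18 and 26 months. That was at least 4183.9-fold higher, but coding copies were not sought. The mitochondrial tRNA gene mt-Ta (chromosome M, 5018 to 5086) had 0 reads in all 12 male libraries and 30.6 ± 6.19 CPM over the 12 female libraries, at least 1450.2-fold lower in males. Short RNA genes took 5.43% ± 0.405 of counts in 2-month males and 4.09% ± 0.515 in 2-month females, and pseudogenes 1.95% ± 0.0625 and 1.37% ± 0.0668 (SD, n = 4).

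Of 16677 genes, 3173 were called, 1749 higher and 1424 lower in males, and 320 and 263 of these differed at least 2-fold. After Defa5 the highest were Rpl19 (3.08 ± 0.05, adjusted p = 2.11e-23), Rpsa with 7 near-identical copies (2.88 ± 0.05), and Rps25 with 2 copies (2.83 ± 0.06). They were followed by RP23-167B4.4, for which no position was found (2.78 ± 0.15), the small GTPase gene Arl5c (1.99 ± 0.19), the dendritic cell gene Lamp3 (1.97 ± 0.18) and mmu-mir-689-2, inside Zc3h7a on the opposite strand (1.80 ± 0.31). Among the 8 lowest were mitochondrial tRNAs without male reads, mt-Ta and, with smaller bounds, mt-Te at least 148.2-fold, mt-Tm at least 140.5-fold, mt-Tq at least 134.3-fold and mt-Tl2 at least 110.4-fold lower. The other 3 were small RNA genes with few male reads, AC162464.1 at 10.3 ± 1.53 CPM, AL772349.1 at 6.71 ± 2.1 CPM and AC069308.1 at 3.98 ± 0.954 CPM in 2-month females. The first lies opposite Gm16630 and the last inside Hydin. Without genes with near-identical copies, pseudogenes and genes under 200 nt, 1489 genes were called, and without the libraries with stomach transcripts 2090.

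Camera called 10 lists between the sexes, and 2 of these with an estimated correlation. The Y-linked genes were all higher in males, 4 of 4, and 4 adjusted over the list alone (camera adjusted p = 2.89e-21; 4.22e-05 with an estimated correlation). The X-linked escape genes with Xist had 4 of 5 lower in males, 5 adjusted over the list alone (median -0.61, camera adjusted p = 1.55e-09; 8.57e-05 with an estimated correlation). The demethylase gene Kdm6a was at -0.85 ± 0.03 and Kdm5c at -0.61 ± 0.04. Ribosomal proteins had 52 of 80 higher and 6 lower, 56 and 9 adjusted over the list alone (median 0.25, camera adjusted p = 5.47e-22; 0.198 with an estimated correlation). Replication-dependent histones had 32 of 59 higher, 39 adjusted over the list alone (median 0.31, camera adjusted p = 4.94e-14; 0.706 with an estimated correlation). Nuclear oxidative phosphorylation had 30 of 73 higher and 3 lower, 33 and 4 adjusted over the list alone (camera adjusted p = 5.16e-06; 0.824 with an estimated correlation). Mitochondrially encoded genes had 11 of 22 lower and 2 higher, 11 and 2 adjusted over the list alone (camera adjusted p = 2.01e-13; 0.0763 with an estimated correlation). The median was -2.57 with the 10 tRNA genes without male reads at their bound. Without short RNA genes the median of that list was 0.05 (adjusted p = 0.556). B cell and plasma cell genes had 8 of 12 higher, 8 adjusted over the list alone (median 1.10, camera adjusted p = 0.0118; 0.824 with an estimated correlation), such as Cd79b (1.24 ± 0.23) and Fcrla (2.83-fold). That list had a median of 0.76 (adjusted p = 0.12) without the 3 shallow libraries and 0.69 (adjusted p = 0.189) without those with stomach transcripts.

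Red blood cell genes had 2 of 5 higher in males, 3 adjusted over the list alone (median 0.72, camera adjusted p = 0.0473; 0.706 with an estimated correlation), Hba-a1 (1.63 ± 0.26) and Hba-a2 (1.48 ± 0.30). Stem cell genes had 4 of 22 lower, 4 adjusted over the list alone (camera adjusted p = 0.0411; 0.824 with an estimated correlation), such as Slc12a2 (-0.28 ± 0.07). Goblet cell genes had 3 of 16 lower, 4 adjusted over the list alone (camera adjusted p = 0.0411; 0.824 with an estimated correlation), such as Galnt12 (-0.25 ± 0.07). Their medians of -0.18 and -0.15 were -0.17 and -0.11 without the 3 shallow libraries (adjusted p = 0.102 and 0.124). Of 15 Paneth cell genes 7 were lower and 1, Defa5, was higher (camera adjusted p = 0.0577), with the list's median at -0.34, and the ileal genes Muc3 (-0.93 ± 0.14) and Fgf15 (-1.82 ± 0.34) were lower in males. The median, mean and test differed in sign in the MHC class I, type I interferon, Paneth cell, clock and proximal small intestine lists.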

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

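The tests of feature length, of mitochondrial tRNA neighbours, of short RNAs and of villus epithelium, and the thinning of libraries, were chosen only after the results they bear on were seen.

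MHC class II genes were higher at 18 and at 26 months in both sexes, with 7 of 11 genes called at each age and a list median of 2.21 and 2.07 on the log2 scale. With an estimated correlation the list was not called (adjusted p = 0.13 and 0.736). A larger share of antigen-presenting immune cells would raise their other markers too, but the median log2 fold change of 28 leukocyte, B cell, dendritic cell and macrophage markers was 0.203 at 26 months (upper quartile 0.345), with 1 called higher and 1 lower. Of the abundant markers, Lcp1 went from 26.5 to 30.5 CPM, Ptprc from 14.0 to 20.5 CPM and Itgam, the one called higher, from 24.6 to 36.9 CPM (0.553). At 18 months that median was 0.535 (upper quartile 0.718) and 5 were called higher, among them Lcp1 and Itgam, so some gain of immune cells may add to the MHC class II signal there without matching its size. Villus epithelium left on the crypts was argued against by the enterocyte list, whose median was 0.0712 with 0 of 22 genes called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. An age-related rise of MHC class II in the crypt cells themselves, or in a few immune cells that each carry more of it, stays open, since counts of whole crypts do not separate cells.

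Histone mRNAs and several short structured RNAs had a more negative change with age in males than in females. The median interaction of the histone list was -0.758 with all libraries thinned to the same total and -0.765 without. Thinning keeps expected ratios, so low male 26-month depth stays untested. A lower recovery of short RNAs in the male 26-month preparations may contribute, since the median interaction of 211 snoRNA, snRNA and other small RNA genes was -0.433, against -0.02 for expression-matched coding genes, with 41 of them called more negative and 1 more positive. The libraries of that group share both sex and age, so that preparation and biology cannot be told apart for these short RNAs. A sex difference in how proliferation changes with age is the biological alternative, and stays untested. Of 31 cell cycle genes 3 had a called negative interaction, and that list was not called with an estimated correlation (adjusted p = 0.608) or without the 5 libraries with stomach transcripts, which leaves 1 male 26-month library (median -0.17, adjusted p = 0.123).

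Ribosomal protein genes, coding genes with pseudogene copies and mitochondrial tRNAs differed between male and female libraries as a mean over the 3 ages, with 52 of 80 ribosomal protein genes higher and 6 lower in males. Of 711 coding genes with a near-identical copy, 7.17% were called with at least a 2-fold sex difference, 49 higher and 2 lower in males, a share 10.6 times that of expression-matched coding genes without a copy (0.677%), which is consistent with reads being placed differently among copies in libraries of each sex. Among single-locus features with at least 1 CPM in females, all 9 mitochondrial tRNAs closed in by genes on both sides had 0 reads in all 12 male libraries, against 0 of 4 with a free side (Fisher exact p = 0.0014). Reads that run past the tRNA and then go uncounted would give this, but stay undecided. The tRNA mt-Tl1 had 6 reads in the 12 male libraries against 5.35 CPM in females. Its 1582 nt to the next counted gene may hold uncounted ones, so it cannot decide. With 40 nt in place of 30 nt as the limit of a closed side, 9 of 11 had 0 male reads. Longer reads in male libraries remain possible but undecided, with 31% of such features under 75 nt (9 of 29) without any male read against 1 of 83 features of 75 to 150 nt. All 9 were mitochondrial tRNAs, and 0 of the 17 other features under 75 nt, from 53 nt up, were without male reads, nor were mt-Tc, mt-Tn and mt-Tp, which goes against an effect of length alone. No sex difference in these or other genes was tested apart from library processing.

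An outlying library was searched for in 150 groups of 4 values, of which chance marks about 1 in 20, and 10 groups had one. Total counts of replicate 2 of the 18-month females were 29776197 against 18212095 to 19864330 in the others of its group, and those of replicate 4 of the 26-month males 10998921 against 4839549 to 5418764. The latter library also had 20551 genes with a count against 19235 to 19398. Its Retnlb level was 45.1 CPM against 0 to 0.83 CPM. The mitochondrial share of replicate 2 of the 2-month males was 1.39% against 1.75 to 1.81%. H2-Aa in replicate 1 of the 18-month females was at 377.3 CPM against 263.8 to 273.7 CPM, and Lgr5 in replicate 3 of that group at 64.9 CPM against 34.6 to 39.6 CPM. In replicate 4 of the 26-month females Serpinb5 was at 19.8 CPM against 9.21 to 10.4 CPM and Col1a1 at 1.11 CPM against 0.673 to 0.711 CPM. Eif2s3y in replicate 1 of the 2-month males was at 92.8 CPM against 77.2 to 78.6 CPM.

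The tests of a difference between sexes in the age change gave 403 genes at 26 months and 1 at 18 months, where 2328 genes had an unadjusted p under 0.05, DESeq2 called 140 and limma-voom 65. By name these were Y_RNA (-2.78), Dnajb9 (1.06), Hist1h2ah (-1.14), Hist1h2be (-1.13) and SCARNA15 (-1.97) at 26 months and Plagl2 (-0.83) at 18 months, as male minus female log2 fold changes. The lists with such a difference had medians of -0.86 for Paneth cell, 0.96 for tuft cell, 0.59 for enterocyte, -0.36 for cell cycle, -0.77 for replication-dependent histones, 0.23 for p53 target, 0.55 for fatty acid oxidation, -0.40 for cholesterol synthesis, 1.22 for xenobiotic, 0.52 for mitochondrially encoded, 1.12 for T cell, -0.87 for immunoglobulin, 2.87 for mast cell and 2.24 for red blood cell genes. None of these lists was called with an estimated correlation, where the smallest adjusted p was 0.456.

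Other splits of the same libraries were counted for each number of calls. For genes, chance was excluded at 26 against 2 months (1 of 100 splits gave as many, the real one 2671, the highest other 672). The same held at 18 against 2 months (1 of 100, 1550 and 0) and between sexes (1 of 100, 3173 and 4). It held within each sex (1 of 35 splits each) at 26 months in females (2127 and 3) and males (1252 and 10). At 18 months it held in females (359 and 1) and males (1634 and 1). It did not hold at 26 against 18 months (2 of 100, 256 and 320). For the interactions, 1 of 100 splits gave as many at 26 months (403 and 216) and 4 at 18 months (1 and 683). Splits can hold part of the age change, so they decide neither interaction. For counts of lists chance was not excluded, with 72 of 100 splits giving as many at 26 against 2 months (11, highest other 24), 57 at 18 against 2 months (11 and 24), 65 at 26 against 18 months (12 and 22), 43 in the interaction at 26 months (14 and 22) and 81 between sexes (10 and 21). Among histone genes, other splits called up to 42 at 26 against 2 months, where the real split called 16 (3 of 100 gave as many, 41 as small a camera p), and up to 45 in the interaction, where it called 35 (2 and 3 of 100).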

How the results depend on the processing

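The 5 alternatives on stomach transcripts, shallow libraries, thinning, short RNA genes and genes with copies were chosen only after the data were seen. Median-of-ratios size factors left every count of calls within 1.5 times its value, and with these factors and TMM no median change of all genes exceeded 0.1. With DESeq2, 26 against 18 months gave 487 genes, 18 against 2 months in females 546, the interactions at 26 and 18 months 818 and 140, and the sex comparison 6 lists. Limma-voom gave 2496 genes at 18 against 2 months, 3807 in females and 830 in males at 26 months, 2680 in males at 18 months, and 741 and 65 for the interactions. Without a low-count filter the interaction at 18 months had 10 genes, the correlation of the sexes was 0.103, and 18 lists were called at 26 against 2 months and 17 between sexes. With at least 1 CPM in at least 8 libraries the 18-month interaction had 0 genes in edgeR, where 2328 had an unadjusted p under 0.05 under the standard filter. A fit of only the libraries compared gave 150 genes at 26 against 18 months, 732 in males at 26 months and 4 in the 18-month interaction.

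An estimated correlation left 0 lists in each age comparison and in the interaction and 2 between sexes, and fry called 7, 4, 0 and 2 in the age comparisons and the interaction. Without the 3 shallow male 26-month libraries, which has fewer samples, 26 against 18 months gave 52 genes and 21 lists, males at 26 months 630 genes and the 18-month interaction 0. That set and the next hold 1 male 26-month library, whose spread comes from the other groups. Without the 5 libraries with stomach transcripts the counts were 1151 at 26 against 2 months, 36 genes and 21 lists at 26 against 18 months, 877 in females and 457 in males at 26 months, 124 and 0 in the interactions, 2090 between sexes and 454 in the overlap. There 26-month Igkc went to -0.10 (females stayed higher) and the enterocyte interaction median to -0.22. With all libraries thinned to 4839549 counts the counts were 1543, 615 and 112 in the comparisons over both sexes, 1150 and 831 at 26 months and 110 and 694 at 18 months in females and males, 0 in the 18-month interaction and 377 in the overlap, so depth limits how many genes are called. Without short RNA genes the 18-month interaction had 0 genes, and the median of mitochondrially encoded genes between sexes reversed to 0.0509. Without genes with copies, pseudogenes and genes under 200 nt it reversed to 0.0635, the 26-month interaction had 254 genes, the sex comparison 1489 genes and 16 lists. Separate 2-month libraries gave an overlap of 313 and 326. Where fewer samples or genes do not show it, the cause was not tested.

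Leaving out single libraries gave 1944 to 2877 genes at 26 against 2 months, 995 to 2029 at 18 against 2 months and 112 to 342 at 26 against 18 months. In females and males at 26 months the ranges were 1246 to 2446 and 634 to 1551, at 18 months 235 to 429 and 495 to 1801, in the interactions 141 to 991 and 0 to 110, and between sexes 2910 to 3364. The correlation ranged from 0.277 to 0.408, the overlap from 602 to 1147, and the lists from 10 to 17, 10 to 15, 8 to 15, 12 to 18 and 7 to 14 in the 5 list comparisons. Libraries are written here as sex, months and replicate. The 18 against 2 month count moved by over 1.5 times without male 2 replicate 1 (995) and female 18 replicate 4 (1023). That of 26 against 18 months did so without female 18 replicate 3 (159), female 26 replicates 2 (148) and 3 (133), male 18 replicates 2 (144), 3 (115) and 4 (157) and male 26 replicates 2 (125) and 3 (112). In females at 26 months it was female 2 replicates 3 (1366) and 4 (1307) and female 26 replicates 2 (1394) and 4 (1246), and in males male 2 replicates 1 (662) and 2 (750) and male 26 replicates 2 (746), 3 (833) and 4 (634). At 18 months in females it was female 2 replicates 2 (235) and 3 (236) and female 18 replicate 2 (236), and in males male 2 replicates 1 (495) and 2 (862) and male 18 replicates 1 (982), 2 (896) and 4 (780). The 26-month interaction moved without female 2 replicates 1 (160) and 3 (212), female 26 replicates 2 (141), 3 (991) and 4 (150), male 2 replicates 1 (267), 2 (166) and 3 (250) and male 26 replicates 3 (172) and 4 (257). That at 18 months went from 1 to 3, 110, 6, 7, 27 and 11 without female 2 replicate 4, female 18 replicates 4 and 3, female 26 replicate 3, male 2 replicate 4 and male 18 replicate 1, and to 0 without female 2 replicates 1 to 3, female 18 replicate 2, female 26 replicate 2, male 2 replicates 1 to 3, male 18 replicates 2 and 4 and male 26 replicates 1 and 4. The 17 lists at 26 against 2 months were those without female 26 replicate 4.

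Of 321 named gene results, 319 kept their call with the other size factors, 315 of 319 with DESeq2, 297 with limma-voom, 306 without a filter, 246 without the shallow libraries, 211 without those with stomach transcripts and 235 of 289 when thinned, and 82 lost it at least once when single libraries were left out. With the replicate number as a block, 308 of the 321 kept their call, the 18-month interaction had 0 genes and the other counts stayed within 1.5 times. The residual correlation of libraries with the same replicate number had a mean of 0.0115 over 60 pairs, 12 of them above 0.1, against -0.00373 over 180 pairs with different numbers, 27 of them above 0.1, and 9 of 24 libraries correlated best with a library of their own number, so the numbers gave no sign of pairing.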

Other observations

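The imprinted gene test and the protocadherin and stomach genes below were chosen after single genes were seen.

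Of the 22 Pcdhb symbols in the counts, protocadherins known as adhesion genes of neurons, 7 passed the low-count filter, and all 7 were called higher at 26 against 2 months over both sexes, with log2 fold changes from 1.56 to 3.14 on chromosome 18 between 37467109 and 37681073 (mm9). Pcdhb17 rose by 3.14 ± 0.35 (SE, adjusted p = 1.1e-06). At 18 months 6 of the 7 were called higher, and Pcdhb22 was not (1.26 ± 0.43, adjusted p = 0.0641). Their mean levels were low, with 1.19 CPM for Pcdhb16, and a rise with age itself helps a gene past the filter. Without the filter, 8 of the 22 were called higher by edgeR, with 17 positive and 5 negative fold changes.

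Transcripts of the stomach lining appeared in replicate 3 of the 2-month females, replicate 2 of the 26-month females and replicates 1 to 3 of the 26-month males. Over these 5 libraries Gkn1 was between 1.54 and 44.4 CPM, Tff2 between 1.60 and 15.8 CPM and Muc6 between 4.04 and 29.8 CPM. In the other 19 libraries their highest levels were 0.0354, 0.39 and 4.36 CPM.

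A hypothesis was that expression of long genes falls relative to short genes with age. Across 13525 coding genes, which are not independent replicates, the Spearman rho of gene span with the 26 against 2 month change was -0.208 in females and -0.101 in males. The slope of log2 CPM against log length went from 0.775 ± 0.0177 to 0.684 ± 0.0134 in females (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give) and from 0.682 ± 0.036 to 0.637 ± 0.028 in males (exact permutation p = 0.0857). The rho was -0.047 in females and -0.168 in males at 18 months. The female values may reflect such a fall or a shift in RNA quality between libraries, and the male values leave it open.

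Genes with CpG-rich promoters might be over-represented among strongly changing genes. Of 33 coding genes that fell at least 4-fold at 26 months, 17 or 51.5% had such a promoter, against 35.1% in expression-matched random sets (percentile 98.4 of 10000). Of 40 that rose at least 4-fold, 4 or 10% did, against 43.4%, the opposite of the prediction for rising genes. The groups differed (two-sided Fisher exact p = 0.000177). Methylation was not analysed here.

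Imprinted genes were tested as a set, since some may fall together with age. Of 34, 4 were higher and 7 lower at 26 months, against 1522 and 1149 of 16677 genes. Their median (-0.03, percentile 25.1 of 10000 random expression-matched lists) did not shift, but cannot exclude a fall of some.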
